A study of Mus musculus with 17 samples.

How the data were processed

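RNA was measured by polyA-selected sequencing in a line of E14Tg2a.4 mouse embryonic stem cells in which the ribosomal protein Rpl31 carries a FLAG-TEV-AviTag. The cells were grown in serum with leukemia inhibitory factor. ALIBi, a proximity biotinylation system, marked ribosomes at the endoplasmic reticulum (ER), and the marked ribosomes were affinity purified. Each lysate also gave a whole-cell library. Cells had received a scramble siRNA, an siRNA against Nmd3 or an siRNA against Gnl3. The 17 libraries fall into 6 groups of siRNA by fraction, with 3 biological replicates each, except scramble ER ribosome-bound RNA with 2 (replicates 2 and 3; replicate 1 is not among the samples used here). The labels name the replicates as biological replicates, and each was taken here as a separate culture.

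The deposited values are raw counts per gene, 1 library per file, with no normalization. Per the labels, the authors used STAR 2.7.9a, HTSeq 0.11.2, DESeq2 with no version given, and the mouse build GRCm39. The annotation release, the strand setting of counting and any read filter are not stated. Each file lists 55416 versioned Ensembl gene IDs and 5 HTSeq lines that name no gene. The latter were left out of all totals and tests. Of their entries, those with no feature were 46.6% to 48.3% of a library, those not unique 5.1% to 10.2% and those ambiguous 0.36% to 0.57%. Symbols came from the GENCODE M21 annotation (GRCm38), which names 52083 of the IDs. No coordinates are given, since that build differs from the authors'. The same annotation gave coding lengths, transcript GC content and the genes lying on opposite strands. Where a named gene overlaps an exon of a gene on the other strand, its value may hold counts of that gene, and the overlap is stated.

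Depth ranged from 15.2 to 29.9 M gene counts per library. Errors on fold changes are standard errors (SE), taken as the absolute log2 fold change divided by the square root of the F statistic. Levels of single libraries are counts per M gene counts (CPM). Levels given in the text as mean ± SD over replicates are CPM further scaled by the TMM factors of the fit used. The mean of the same group can therefore differ between comparisons that come from different fits.

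Groups were compared in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test (filterByExpr, TMM scaling, robust glmQLFit, glmQLFTest). P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons of ER ribosome-bound with whole-cell RNA, and the interactions (the difference of that ratio between a knockdown and scramble), used 1 fit of all 17 libraries with 18525 genes. Knockdowns were compared with scramble, and with each other, in a fit of the 9 whole-cell libraries (17310 genes) and a fit of the 8 ER ribosome-bound libraries (17632 genes). The main tests used no replicate block, although each lysate gave both fractions, which pairs them by design. A block was tried as an alternative. Across genes, residuals of libraries with the same number in both fractions of an siRNA correlated between -0.19 and 0.1 (0.07 to 0.1 in scramble). For Nmd3 and Gnl3 these residuals hold the whole-cell libraries that stood apart. They therefore cannot show that pairing is absent. Among groups that were compared, only scramble and Nmd3 whole-cell libraries paired by number (0.21 to 0.49).

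The 32 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 3, preset inter-gene correlation 0.01). Adjustment ran over all 32 lists in the 11 comparisons, 352 tests in all. camera compares a list with all other genes tested, so a listed direction is relative to them. The lists were cytosolic ribosomal proteins of the large and of the small subunit, 60S subunit maturation and export, small subunit processome and 40S maturation, p53 target genes, and integrated stress response (ATF4) targets. They further held ER chaperones and unfolded protein response, and secreted and extracellular matrix proteins. Next were plasma membrane receptors and adhesion proteins, solute carriers and ion transporters, Golgi and glycosylation enzymes, lysosomal proteins, cholesterol biosynthesis, and signal recognition and translocon machinery. They also held the nuclear-encoded mitochondrial ribosome and respiratory chain, mitochondrially encoded mRNAs, proteasome subunits, glycolytic enzymes, translation initiation and elongation factors, snoRNA host genes and nuclear-retained long noncoding RNAs. The cell state lists were pluripotency factors, totipotent 2-cell-like genes, primitive endoderm markers, epiblast and germ layer differentiation markers, fibroblast and feeder cell markers, interferon and double-stranded RNA response, apoptosis, DNA replication, mitosis, heat shock proteins, and the cytoskeleton.

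The samples' groups, the tests, the lists and the rule for naming genes were set before the data were examined. The rule names Nmd3 and Gnl3 in every library. In each comparison it then names called protein-coding genes with a mean log2 CPM of at least 3 and no overlap between the groups' CPM. Of these it takes the 10 with the largest positive and the 10 with the largest negative change (5 and 5 for interactions and for Nmd3 against Gnl3). From each list it takes the 2 called members with the largest change in each direction, or, with none called, the member with the highest mean CPM.

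The correlation of the knockdowns' effects was Pearson's r across genes, on log2 CPM with 0.5 CPM added, set beside 20 simulations of unchanged groups that share their scramble libraries. Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no filter on low counts, a filter of 5 CPM in 2 libraries, another set of libraries in the fit, a replicate block, and leaving out each library in turn. For camera an estimated inter-gene correlation and a block were tried, and for the correlation genes of log2 CPM 5 or more. Leaving out both whole-cell libraries that stood apart was chosen after seeing the data. Trends with coding length and GC content were fitted by loess with a span of 0.5 on genes of mean log2 CPM of at least 1, and of at least 3 for the trends within single whole-cell libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

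The test was tried on simulated data with the spread of these libraries and 50 genes of log2 CPM over 2 changed at each fold. For Nmd3 siRNA against scramble on ER ribosomes it found 44% of genes changed by 0.32 on the log2 scale, 90% of genes changed 1.5-fold and 98% of those changed 2-fold. For the same comparison in whole-cell RNA with all libraries it found 0% at 1.5-fold, 6% at 2-fold and 78% at 4-fold. Without both libraries that stood apart it found 80%, 96% and 100%, and 42% at 0.32 on the log2 scale. For the scramble enrichment it found 2%, 30% and 92%, and for the Nmd3 interaction 0%, 14% and 82% (64%, 90% and 98% without both). Unchanged genes were also called, over all folds together: 11 on ER ribosomes, and 4 in whole-cell RNA (12 without both). For the scramble enrichment 1 was called, and for the Nmd3 interaction 5 (14 without both). camera found a simulated list of 40 raised genes in each design, and gave p under 0.05 to between 1 and 3 of 100 random lists. The simulated genes varied independently of each other, so this could not check the preset inter-gene correlation.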

Results

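The data are gene counts of polyA RNA from mouse embryonic stem cells, taken from ribosomes purified at the ER and from the whole-cell lysate, after scramble, Nmd3 or Gnl3 siRNA. Scramble whole-cell libraries held 15.9, 17.8 and 22.8 M gene counts, and the scramble ER ribosome-bound libraries 18.5 and 18.9 M. Nmd3 siRNA gave 16, 22.8 and 17.9 M in whole-cell RNA and 16.6, 20.3 and 19.6 M on ER ribosomes. Gnl3 siRNA gave 15.2, 18.7 and 20.3 M in whole-cell RNA and 22.1, 29.9 and 16.3 M on ER ribosomes. Between 19850 and 24859 genes had a count in a library. Log2 CPM correlated across genes between 0.989 and 0.997 among the 8 ER ribosome-bound libraries, and between 0.99 and 0.997 among 7 of the whole-cell libraries. The other 2, Gnl3 whole-cell replicate 3 and Nmd3 whole-cell replicate 2, correlated with those 7 at only 0.845 to 0.905. Mitochondrial RNA made up 6.14% of counts in the former and 0.769% in the latter, against 1.15% in Nmd3 whole-cell replicate 1 and 1.86% to 2.03% in the remaining whole-cell libraries. With both in the fit, the biological coefficient of variation was 0.316 among whole-cell libraries, and without them 0.059. Among ER ribosome-bound libraries it was 0.065. For Nmd3 ER ribosome-bound replicate 2 the highest r with another ER ribosome-bound library was 0.991, against 0.996 or 0.997 for the rest. Its counts differed from those of replicates 1 and 3 by a chi-square of 9.3 and 11.04 per gene, against 3.27 between those replicates. The list tests were not repeated without it.

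Nmd3, the adaptor that takes the large ribosomal subunit out of the nucleus (ENSMUSG00000027787.15), was at 153, 153.8 and 150.2 CPM in scramble whole-cell RNA, and at 123.7 and 120 CPM on scramble ER ribosomes. After Nmd3 siRNA it was at 43.7, 72.3 and 43.2 CPM in whole-cell RNA, and at 25.2, 24.1 and 25.2 CPM on ER ribosomes. After Gnl3 siRNA Nmd3 was at 151.5, 142.2 and 273.7 CPM in whole-cell RNA, the last in the replicate that stood apart, and at 124.5, 119.7 and 119.7 CPM on ER ribosomes. Gnl3, a nucleolar GTPase also called nucleostemin (ENSMUSG00000042354.8, which overlaps Pbrm1 on the other strand), was at 272, 270.1 and 256 CPM in scramble whole-cell RNA, and at 170 and 177.4 CPM on scramble ER ribosomes. After Gnl3 siRNA it was at 70.2, 54.2 and 88.2 CPM in whole-cell RNA, and at 31.6, 26.9 and 29.7 CPM on ER ribosomes. After Nmd3 siRNA Gnl3 was at 279.9, 275.8 and 267.7 CPM in whole-cell RNA, and at 164.2, 262.9 and 179.8 CPM on ER ribosomes. On ER ribosomes Nmd3 fell by 2.29 on the log2 scale after its siRNA (SE 0.06, adjusted p = 2.42e-20) and Gnl3 by 2.58 after its own (SE 0.24, adjusted p = 0.0092). In whole-cell RNA edgeR called neither with all libraries: Nmd3 differed by -1.29 (SE 0.39, adjusted p = 0.852) and Gnl3 by -1.84 (SE 0.25, adjusted p = 0.462). DESeq2 did call Gnl3, as did edgeR with all 17 libraries in the fit or without a filter on low counts. Without both libraries that stood apart Nmd3 fell by 1.81 (SE 0.07, adjusted p = 7.92e-19) and Gnl3 by 2.1 (SE 0.08, adjusted p = 5.48e-13).

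**Figure D1:**
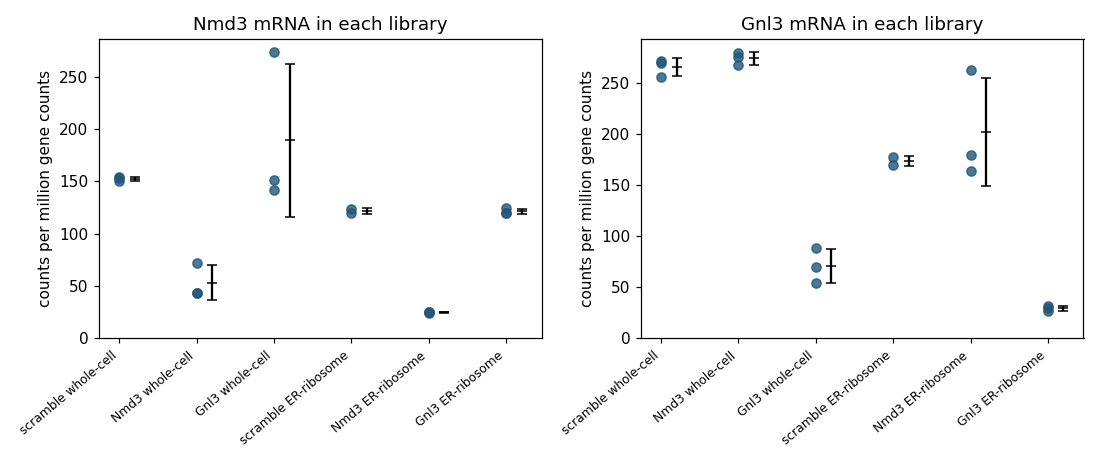
Counts per M gene counts of Nmd3 (left) and Gnl3 (right) in each of the 17 libraries, by siRNA and fraction, with the mean and SD of each group beside the points. On ER ribosomes the Nmd3 siRNA libraries sit between 24.1 and 25.2 CPM for Nmd3, and the Gnl3 siRNA libraries between 26.9 and 31.6 CPM for Gnl3.

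The first comparison asks which mRNAs were on ER ribosomes more than in the whole cell, in scramble siRNA cells. Apoe, a secreted lipid carrier, was at 1393 ± 18.8 CPM on ER ribosomes (n = 2) and 487.6 ± 11.9 CPM in whole-cell RNA (n = 3), a log2 change of 1.51 (SE 0.17, adjusted p = 0.000146). Trh, the thyrotropin-releasing hormone precursor, was at 360.9 ± 3.57 against 132.3 ± 2.43 CPM, a log2 change of 1.45 (SE 0.19, adjusted p = 0.000381). The growth factor Mdk (1.46, SE 0.31), the oligosaccharyltransferase subunit Dad1 (1.44, SE 0.23), the secreted Wfdc2 (1.44), the protease inhibitor Spint2 (1.43) and the ER enzyme Vkorc1 (1.43) also rose. Mitochondrially encoded mRNAs, which mitochondrial ribosomes translate, fell most. mt-Co1 (opposite mt-Ts1) was at 99.95 ± 1.41 against 7983 ± 362 CPM (-6.32). mt-Cytb was at 18.74 ± 1.3 against 2934 ± 172 CPM (-7.29, SE 0.51, adjusted p = 1.85e-06). Among nuclear-encoded mRNAs Bod1l was at 6.638 ± 0.019 against 63.27 ± 7.84 CPM (-3.25, SE 0.5, adjusted p = 0.00086), the microtubule-associated Map1b changed by -3.13 (SE 0.44) and Mdn1, an ATPase of large-subunit assembly, by -2.98 (SE 0.39).

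Of 46 lysosomal protein mRNAs 31 rose and 0 fell (40 and 0 adjusted over the list alone), with a median log2 change of 0.8 (camera adjusted p = 3.5e-20, and adjusted p = 0.011 with an estimated correlation). They included the protease Ctsz (1.3, SE 0.17; opposite Nelfcd) and the cholesterol carrier Npc2 (1.26, SE 0.25). Of 37 ER chaperone and unfolded protein response mRNAs 23 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.72 (adjusted p = 4.9e-14, and adjusted p = 0.014 with an estimated correlation). Neither the lysosomal list nor this one passed with an estimated correlation without both libraries that stood apart (adjusted p = 0.26 and 0.24). Sdf2l1 rose by 1.33 (SE 0.25). Of 49 secreted and matrix protein mRNAs 20 rose and 0 fell (23 and 2 adjusted over the list alone, median 0.58, adjusted p = 3.2e-06, and adjusted p = 0.33 with an estimated correlation). Igfbp2 rose by 1.37 (SE 0.36). Of 35 mRNAs of the signal recognition and translocon machinery 16 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.61, adjusted p = 6.3e-08, and adjusted p = 0.18 with an estimated correlation). The ribosome receptor Rrbp1 was the one that fell, with a log2 change of -1.37. Of 50 Golgi and glycosylation mRNAs 13 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.28, adjusted p = 7.8e-05, and adjusted p = 0.67 with an estimated correlation). Ddost rose by 1.19 (SE 0.13). Of 46 solute carriers 7 rose and 0 fell, as over the list alone (median 0.28, adjusted p = 0.0016, and adjusted p = 0.67 with an estimated correlation). Of 61 plasma membrane receptors 11 rose and 3 fell (11 and 4 adjusted over the list alone, median 0.2, adjusted p = 0.0058, and adjusted p = 0.75 with an estimated correlation). Sdc4 (1.43, SE 0.2) and Bsg (1.35, SE 0.2) were highest, while the very long mRNA of the endocytic receptor Lrp2 fell by 1.57 (SE 0.34).

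All 11 mitochondrially encoded mRNAs tested fell (adjusted p = 1.9e-22, and adjusted p = 0.065 with an estimated correlation). The 7 abundant ones changed by -5.98 to -7.29, and the median was -6.52 with the 4 members that had at most 3 counts over the ER ribosome-bound libraries held at 3 counts. Of 17 nuclear-retained long noncoding RNAs 6 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.83, adjusted p = 1.4e-06, and adjusted p = 0.088 with an estimated correlation). Rian changed by -2.98 (SE 0.19) and Malat1 by -2.93 (SE 0.26; opposite Gm37376). Of 50 small subunit processome mRNAs 12 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.34, adjusted p = 6.8e-05, and adjusted p = 0.29 with an estimated correlation). Utp20 fell, with a log2 change of -2.32 (SE 0.22). Of 55 mRNAs of 60S maturation 9 fell and 0 rose (11 and 0 adjusted over the list alone, median -0.11, adjusted p = 0.015, and adjusted p = 0.54 with an estimated correlation). Of 43 mitosis mRNAs 15 fell and 0 rose (17 and 0 adjusted over the list alone, median -0.25, adjusted p = 1.8e-05, and adjusted p = 0.36 with an estimated correlation). The kinetochore genes Knl1 (-2.95, SE 0.39) and Cenpf (-2.57, SE 0.27) were among them. Of 43 DNA replication mRNAs 8 fell and 1 rose, as over the list alone (median -0.12, adjusted p = 0.019, and adjusted p = 0.66 with an estimated correlation).

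The ribosomal protein lists rose as groups with no member called: the 49 large-subunit mRNAs had a median of 0.44 (adjusted p = 0.0011, and adjusted p = 0.8 with an estimated correlation) and the 33 small-subunit mRNAs 0.45 (adjusted p = 0.0081, and adjusted p = 0.82 with an estimated correlation). Without both libraries that stood apart 42 and 32 of them rose, and 0 and 1 fell. The 52 nuclear-encoded mitochondrial mRNAs (3 rose, 2 fell, median 0.3, adjusted p = 0.0085), the 47 p53 targets (6 rose, 1 fell, median 0.19, adjusted p = 0.048, and 0.063 with the culture as a block) and the 21 totipotent 2-cell-like genes (2 rose, 0 fell, median 0.53, adjusted p = 0.049) also passed. With an estimated correlation their adjusted p was 0.82, 0.36 and 0.59. After a trend with coding length was taken off, the medians were 0.02 and 0.06 (ribosomal proteins), 0.01 (nuclear-encoded mitochondrial) and 0.08 (p53 targets). Only 47.6% of the 2-cell-like members had a value, too few for that check. The lists that did not pass were cholesterol biosynthesis (5 of 26 rose, 1 fell, median 0.36, adjusted p = 0.084), fibroblast and feeder markers (3 of 19 rose, 0 fell; 0.32, 0.058), proteasome subunits (0 of 32 rose, 1 fell; 0.22, 0.18) and pluripotency factors (4 of 36 rose, 3 fell; 0.14, 0.57). Others were apoptosis (1 of 28 rose, 1 fell; 0.12, 0.67), integrated stress response targets (2 of 34 rose, 2 fell; 0.05, 0.79), heat shock proteins (0 of 25 called; 0.04, 0.81), glycolytic enzymes (0 of 17 rose, 1 fell; -0.06, 0.54), translation factors (0 of 42 rose, 6 fell; -0.01, 0.41) and primitive endoderm markers (2 of 24 rose, 1 fell; -0.25, 0.84). In a further 4 the median and the mean differed in sign: snoRNA host genes (0 of 17 rose, 4 fell, median 0.19, mean -0.24, adjusted p = 0.32), epiblast markers (0 of 26 rose, 3 fell; 0.02, -0.06, 0.62), interferon response (1 of 21 rose, 1 fell; -0.02, 0.02, 0.74) and cytoskeleton (0 of 37 rose, 3 fell; 0.01, -0.1, 0.93).

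In all, 2353 genes passed, 952 higher and 1401 lower on ER ribosomes (40.5% higher; 52.9% when only library totals were scaled). With the culture as a block 386 passed, and with only the scramble libraries in the fit 9859. Of 88 results on single genes in this comparison, 47 lost their call with the block. Leaving out 1 library gave 1337, 1549 and 1366 genes (scramble whole-cell replicates 1, 2 and 3), 541 (ER ribosome-bound replicate 2) and 671 (replicate 3). Without both libraries that stood apart, which share the estimate of spread, 9197 passed, 4579 higher and 4618 lower. With the culture as a block and without both, 8650 passed.

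**Figure D2:**
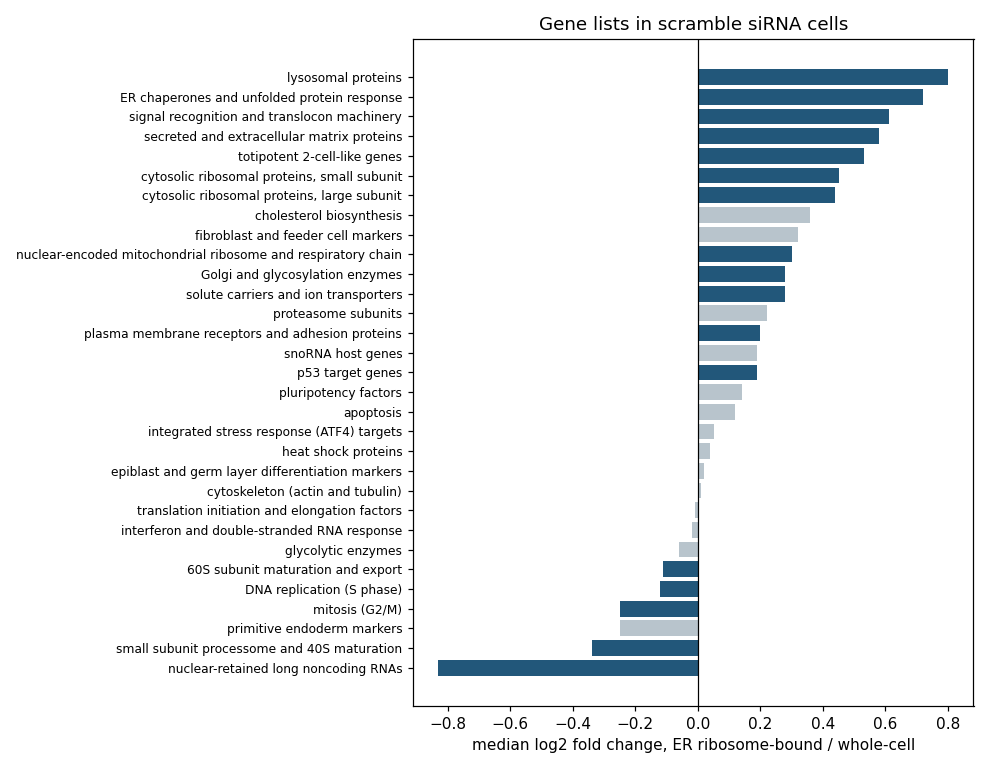
Median log2 fold change of ER ribosome-bound over whole-cell RNA in scramble siRNA cells for 31 gene lists, with lists at a camera adjusted p under 0.05 in dark bars and the others in light bars; the mitochondrially encoded mRNAs, far lower, are left out. Lysosomal (0.8) and ER chaperone (0.72) lists have the highest medians and nuclear-retained long noncoding RNAs the lowest (-0.83).

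The same contrast after Nmd3 siRNA asks which mRNAs were on ER ribosomes when large-subunit export was targeted. The macrophage and lysosomal glycoprotein Cd68 was at 33.13 ± 0.87 CPM on ER ribosomes and 9.864 ± 4.06 CPM in whole-cell RNA (n = 3 each; log2 change 1.75, SE 0.25, adjusted p = 0.000295). Nucb1 (1.67, SE 0.18), the lysosomal Gm2a (1.65, SE 0.18) and Tpp1 (1.59, SE 0.28) and the surface glycoprotein Thy1 (1.55, SE 0.15) rose too. Bod1l (-2.44), Cenpf (-2.35) and Rif1 (-2.32) fell. These sizes include Nmd3 whole-cell replicate 2, which stood apart. Of the lysosomal list 36 of 46 rose and 0 fell (42 and 1 adjusted over the list alone, median 0.93, adjusted p = 2.4e-25, and adjusted p = 0.01 with an estimated correlation). Of the ER chaperone list 25 of 37 rose and 0 fell (27 and 0 adjusted over the list alone, median 0.75, adjusted p = 1.4e-17, and adjusted p = 0.01 with an estimated correlation). For each list the latter was 0.24 without both libraries that stood apart. Secreted proteins (25 of 49 rose, 0 fell, median 0.7, adjusted p = 7.2e-13) and plasma membrane receptors (28 of 61 rose, 1 fell; 0.63, 1.5e-12) passed with the preset correlation. With an estimated correlation their adjusted p was 0.097 and 0.46. Mitochondrially encoded mRNAs fell, 11 of 11 (adjusted p = 3.8e-22, and adjusted p = 0.065 with an estimated correlation), mt-Cytb with a log2 change of -6.72. The ribosomal protein lists had medians of -0.39 (adjusted p = 0.35) and -0.47 (adjusted p = 0.32), and without Nmd3 whole-cell replicate 2 and the other library that stood apart 0.37 and 0.43, with 43 of 49 and 30 of 33 members higher. The totipotent 2-cell-like list was not called (adjusted p = 0.06) and with the culture as a block it was (0.03). Its adjusted p with an estimated correlation and no block was 0.6. In all, 2819 genes passed, 1429 higher and 1390 lower (50.7% higher; 70.4% with library totals only, which moved the median of all genes from -0.108 to 0.046). The block gave 1320, and a fit of only the Nmd3 siRNA libraries 729. Of 86 results on single genes, 26 lost their call with the block. Without both libraries that stood apart, and without the block, all 86 kept the same side of the threshold and direction. Without ER ribosome-bound replicate 1, 2 or 3 there were 1815, 1785 and 1819, and without whole-cell replicate 2 there were 5421. Without both libraries there were 9152, 4473 higher and 4679 lower, and 8543 with the block.

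After Gnl3 siRNA the same contrast was led by Rabac1, a prenylated Rab acceptor of the Golgi (1.87, SE 0.49, adjusted p = 0.0116), the proton pump subunit Atp6v0c (1.85, SE 0.43), Cyba (1.83), Wfdc2 (1.81) and the receptor Cd320 (1.75, SE 0.31). mt-Cytb (-7.91, SE 0.43), Bod1l (-3.36), Map1b (-3.28) and Knl1 (-3.02) fell. These sizes include Gnl3 whole-cell replicate 3, which stood apart. Lysosomal mRNAs (37 of 46 rose, 0 fell; 40 and 1 adjusted over the list alone, median 0.87, adjusted p = 2e-16, and adjusted p = 0.016 with an estimated correlation) and ER chaperones (27 of 37 rose, 0 fell; 30 and 1 adjusted over the list alone, median 0.78, adjusted p = 4.2e-12, and adjusted p = 0.019 with an estimated correlation) rose again. Each list had an adjusted p of 0.24 with an estimated correlation and without both libraries that stood apart. Small subunit processome mRNAs (0 of 50 rose, 22 fell, median -0.4, adjusted p = 6.2e-05, and adjusted p = 0.29 with an estimated correlation) and mitosis mRNAs (0 of 43 rose, 19 fell, median -0.45, adjusted p = 3.2e-06, and adjusted p = 0.33 with an estimated correlation) fell. With the culture as a block the small-subunit ribosomal proteins passed (adjusted p from 0.07 to 0.048) and DNA replication did not (0.029 to 0.057). Neither passed with an estimated correlation and no block (adjusted p = 0.89 and 0.67). In all, 4540 genes passed, 1910 higher and 2630 lower (42.1% higher; 53.7% with library totals only), 2975 with the block, and 8795 without both libraries, 4251 higher and 4544 lower. With the block and without both libraries 8412 genes passed. With the block and all libraries, 15 of 107 results on single genes after Gnl3 siRNA lost their call. Without both libraries and without the block, 104 of the 107 kept the same side of the threshold and direction, and 2 lost their call. Of the 2353 genes called in scramble cells 2346 changed in the same direction after Nmd3 siRNA and 2347 after Gnl3 siRNA. The genes called higher both in scramble cells and after Nmd3 siRNA numbered 748, and those called lower 977. With Gnl3 siRNA these were 882 and 1330.

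Whether a knockdown changed the enrichment itself was tested as an interaction. For Nmd3, edgeR called 0 genes (366 at an unadjusted p under 0.05; DESeq2 0), and 0 without both libraries (1078; 1 with the culture as a block; DESeq2 2). For Gnl3, edgeR called 0 (177; DESeq2 0), and 0 without both (649; DESeq2 0). Scaling by library totals moved the median of all genes in the Nmd3 interaction from 0.015 to 0.124. The interaction of Nmd3's own mRNA with its siRNA was -0.97 (SE 0.44, adjusted p = 0.91) and that of Gnl3's with its own -0.71 (SE 0.32, adjusted p = 1). List values for the interactions are given among the additional observations.

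Gnl3 siRNA against scramble on ER ribosomes asks how mRNA levels there changed when Gnl3 was lowered. These levels are not scaled to whole-cell RNA, so a change may also lie in the whole cell. Perp, a p53-induced desmosomal protein, was at 157.8 ± 6.84 CPM (n = 3) against 93.76 ± 4.5 CPM (n = 2), a log2 change of 0.75 (SE 0.06, adjusted p = 4.95e-09). Anxa1 (1.03, SE 0.17; 10.12 ± 1.39 against 4.945 ± 0.0637 CPM), the receptor kinase Tek (0.9, SE 0.12), the keratin Krt19 (0.78, SE 0.15), Emp1 (0.7, SE 0.08) and the small GTPase Rhob (0.68, SE 0.07) rose. Trh fell by 0.73 on the log2 scale (SE 0.05, adjusted p = 1.67e-10; 226.3 ± 11.4 against 374.9 ± 4.26 CPM), as did Fgf15 (-0.67; opposite Gm26793), the glutathione-degrading Chac1 (-0.63, SE 0.09), the activin subunit Inhbb (-0.59, SE 0.07), the germline factor Dppa3 (-0.58) and the Wnt effector Lef1 (-0.56, SE 0.06; opposite Gm43352).

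The p53 targets rose as a group on ER ribosomes: 19 of 47 rose and 1 fell (33 and 2 adjusted over the list alone), with a median of 0.21 (adjusted p = 3.7e-13, and adjusted p = 0.029 with an estimated correlation). The latter was 0.13 when the comparisons with whole-cell libraries, adjusted together with this one, were refitted without both libraries that stood apart. Cd80 rose by 0.79 (SE 0.19) and Tigar fell (-0.3, SE 0.06; opposite Platr31). Among members chosen after their values were seen, Plk2 rose by 0.6, Trp53inp1 by 0.46, Phlda3 by 0.42 and Mdm2, the p53 ubiquitin ligase, by 0.35. Cdkn1a (0.15, adjusted p = 0.27; opposite AC167363.2), Ccng1 (0.2, adjusted p = 0.0955) and Bax (-0.05, adjusted p = 0.781) were not called. The ATF4 targets fell: 10 of 34 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.21, adjusted p = 2.5e-08, and adjusted p = 0.38 with an estimated correlation). Chac1 and the alanine transaminase Gpt2 (-0.47, SE 0.07) fell and Ddit4 rose (0.19). Also chosen after their values were seen, the serine synthesis enzyme Psat1 (-0.33), Nupr1 (-0.44) and Pck2 (-0.38; opposite Gm10876) fell, and Atf4 (-0.09, adjusted p = 0.376) and Asns (-0.16, adjusted p = 0.146) were not called. Secreted proteins (11 of 48 rose, 0 fell; 14 and 0 adjusted over the list alone, median 0.15, adjusted p = 7.5e-06, and adjusted p = 0.6 with an estimated correlation) and plasma membrane receptors (6 of 61 rose, 1 fell; 11 and 2 adjusted over the list alone, median 0.14, adjusted p = 2.3e-06, and adjusted p = 0.67 with an estimated correlation) rose, among them Ccn2 (0.52; opposite Gm15270) and Epha2 (0.43). Fibroblast and feeder markers (2 of 18 rose, 0 fell; 3 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.00087, and adjusted p = 0.18 with an estimated correlation) and primitive endoderm markers (4 of 24 rose, 0 fell, as over the list alone, median 0.23, adjusted p = 0.00026, and adjusted p = 0.4 with an estimated correlation) moved with them. The secreted list holds 3 and 7 of the genes of these lists. Of 26 cholesterol synthesis mRNAs 5 rose and 0 fell, as over the list alone (median 0.16, adjusted p = 1.9e-06, and adjusted p = 0.18 with an estimated correlation). Insig1 rose by 0.42. Ribosomal protein mRNAs were slightly lower: 5 of 49 of the large subunit fell and 0 rose (32 and 0 adjusted over the list alone, median -0.11, adjusted p = 7.1e-11) and 3 of 33 of the small subunit (21 and 0 adjusted over the list alone, median -0.1, adjusted p = 6e-07). With an estimated correlation their adjusted p was 0.6 and 0.66. Across all genes with a known length the change rose with coding length (Spearman's rho 0.16 across genes, which are not independent replicates). Of 36 pluripotency factors 7 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.06, adjusted p = 0.0073, and adjusted p = 0.38 with an estimated correlation). The metabolic enzyme Tdh fell (-0.36; opposite Gm17232) and Dnmt3l rose (0.3; opposite Aire).

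In all, 472 genes passed in this comparison, 266 higher and 206 lower, with a median absolute log2 change of 0.34 and 15 at 2-fold or more. DESeq2 called 383. With all 17 libraries in the fit, whose biological coefficient of variation was 0.236, edgeR called 1 gene, Gnl3 itself. Leaving out scramble ER ribosome-bound replicate 2 or 3, which leaves 1 scramble library, gave 70 and 120 genes. Leaving out Gnl3 replicate 1, 2 or 3 gave 211, 299 and 253.

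Nmd3 siRNA against scramble on ER ribosomes asks the same of Nmd3. The matrix protein Tinagl1 was at 15.43 ± 1.97 CPM (n = 3) against 8.824 ± 0.332 CPM (n = 2), a log2 change of 0.81 (SE 0.13, adjusted p = 0.000998). Tek (0.67, SE 0.12), the secreted protease Htra1 (0.64, SE 0.1) and Cmtm6 (0.58, SE 0.05; 147.4 ± 5.5 against 98.31 ± 0.431 CPM) also rose. Impact, an inhibitor of the eIF2 alpha kinase Gcn2, was at 160 ± 6.22 against 234.8 ± 6.37 CPM (-0.55, SE 0.05, adjusted p = 9.15e-08). Mroh1 (-0.86, SE 0.11; opposite Bop1), the protein kinase A subunit Prkar2a (-0.63, SE 0.06) and the retinoic acid carrier Crabp2 (-0.59) fell. Of 48 secreted protein mRNAs 8 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.18, adjusted p = 2.3e-07, and adjusted p = 0.52 with an estimated correlation). Bmp4, which lies opposite Gm15217, rose by 0.43. Primitive endoderm markers moved with them (1 of 24 rose, 0 fell, 3 and 0 adjusted over the list alone, median 0.23, adjusted p = 0.00056, and adjusted p = 0.45 with an estimated correlation), and fibroblast and feeder markers were not called (0 of 18, median 0.01, adjusted p = 0.39). Of 46 lysosomal mRNAs 4 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.14, adjusted p = 6.6e-07, and adjusted p = 0.6 with an estimated correlation). Of 26 cholesterol synthesis mRNAs 3 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.15, adjusted p = 8.2e-07, and adjusted p = 0.18 with an estimated correlation). Msmo1 rose by 0.38. Ribosomal protein mRNAs were slightly lower, with medians of -0.07 for both subunits (adjusted p = 3.7e-05 and 0.00014, and adjusted p = 0.71 for each with an estimated correlation); 2 of 49 and 1 of 33 fell. As after Gnl3 siRNA, which was set against the same 2 scramble libraries, the change on ER ribosomes rose with coding length across genes (Spearman's rho 0.13), and between the knockdowns rho was -0.02. The p53 targets (2 of 47 rose, 0 fell, median 0.04, adjusted p = 0.37) and the ATF4 targets (2 of 34 rose, 0 fell, median -0.02, adjusted p = 0.38) were not called. In all, 206 genes passed, 115 higher and 91 lower, with a median absolute log2 change of 0.34 and 4 at 2-fold or more. DESeq2 called 202. With all 17 libraries in the fit edgeR called 0 genes (228 at an unadjusted p under 0.05), so that Nmd3 itself was not called. Without a filter on low counts 407 passed. Without scramble replicate 2 or 3 there were 25 and 23 calls, and without Nmd3 ER ribosome-bound replicate 2 there were 366.

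Compared directly on ER ribosomes, the knockdowns differed in 387 genes, 174 higher and 213 lower after Nmd3 siRNA than after Gnl3 siRNA. The receptor Notch4 (0.76) and Inhbb (0.7, SE 0.06) were higher after Nmd3 siRNA, and Mroh1 (-0.76), Anxa1 (-0.7), the neural factor Sox1 (-0.65) and Impact (-0.65, SE 0.04) lower. Of 47 p53 targets 20 were lower and 0 higher (29 and 2 adjusted over the list alone, median -0.23, adjusted p = 3.8e-13, and adjusted p = 0.029 with an estimated correlation, or 0.13 with the comparisons with whole-cell libraries refitted without both). Of 34 ATF4 targets 10 were higher and 1 lower (22 and 2 adjusted over the list alone, median 0.19, adjusted p = 4.9e-08, and adjusted p = 0.4 with an estimated correlation). Of 36 pluripotency factors 7 were higher and 1 lower (13 and 2 adjusted over the list alone, median 0.08, adjusted p = 0.00059, and adjusted p = 0.29 with an estimated correlation). Tcl1 was higher by 0.4 and Prdm14 by 0.37. Of 28 apoptosis genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone, median -0.1, adjusted p = 0.0021, and adjusted p = 0.18 with an estimated correlation). Pmaip1 changed by -0.42. It is also on the p53 list, as are Bax and Bbc3, so these lists are not separate results. Without Gnl3 ER ribosome-bound replicate 1, 2 or 3 there were 159, 206 and 204 calls, and without Nmd3 replicate 2 there were 703. With all 17 libraries in the fit edgeR called 2 genes, Gnl3 and Nmd3, and without a filter on low counts 586. DESeq2 called 313, and 45% of the edgeR calls were higher (34.8% with library totals only).

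**Figure D3:**
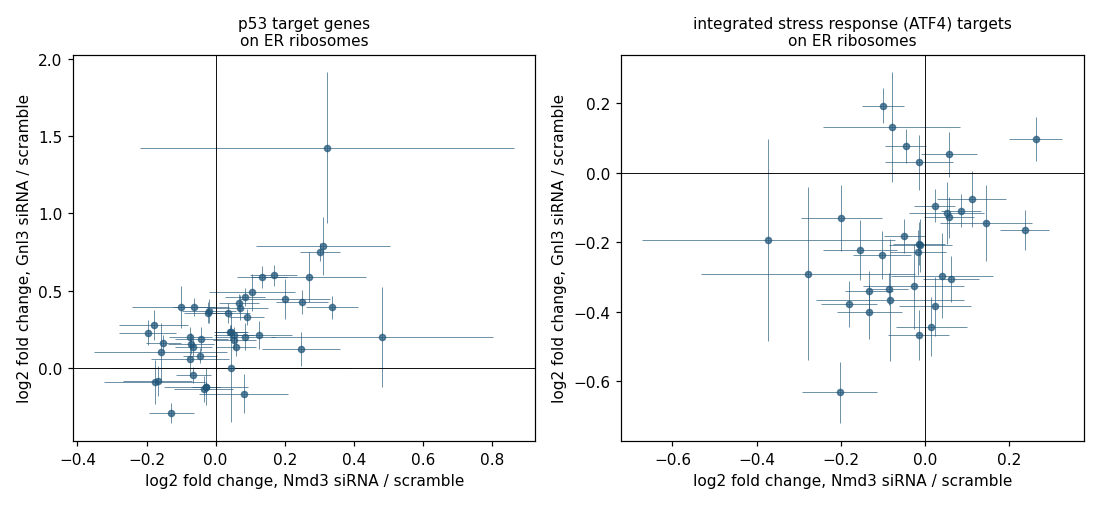
Log2 fold change on ER ribosomes after Gnl3 siRNA (y axis) against that after Nmd3 siRNA (x axis), each against scramble, for the members of the p53 target list (left) and the ATF4 target list (right); points are genes and bars are ± 1 SE. The p53 targets lie mostly above 0 on the y axis (median 0.21) and around 0 on the x axis (median 0.04), and the ATF4 targets mostly below 0 on the y axis (median -0.21).

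The effects of both knockdowns on ER ribosomes were set against the same 2 scramble libraries. The 115 genes higher after Nmd3 siRNA and the 266 higher after Gnl3 siRNA had 63 in common (1.7 if independent; at most 1 in 20 simulations of unchanged groups with shared scramble libraries). The 91 and 206 lower genes had 28 in common (1.1 if independent; at most 2 simulated). The simulations hold no effect and so have few calls to share, and part of the excess may come from the shared scramble libraries. Across 17630 genes, which are not independent replicates, the effects correlated at r = 0.59, beside 0.61 in the simulations, which hold no effect but the same shared libraries. The covariance was 0.0246 beside 0.0178. In whole-cell RNA r was 0.16 (0.5 simulated), and 0.38 without both libraries that stood apart (0.39 simulated). The simulated libraries were independent, whereas scramble and Nmd3 whole-cell libraries paired by number, so the simulated values there are only a rough reference.

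In whole-cell RNA Gnl3 siRNA against scramble gave 0 calls by edgeR with all libraries (199 genes at an unadjusted p under 0.05; DESeq2 1). With all 17 libraries in the fit, or without a filter on low counts, it called 1, Gnl3 itself. Without Gnl3 whole-cell replicate 3 and Nmd3 whole-cell replicate 2, a choice made after seeing the data, 142 genes passed, 90 higher and 52 lower (DESeq2 114). Perp was at 59.64 ± 1.32 CPM (n = 2) against 38.07 ± 1.37 CPM (n = 3), a log2 change of 0.64 (SE 0.07, adjusted p = 5.34e-06). Plk2 (0.65, SE 0.08) and the differentiation inhibitor Id1 (0.66, SE 0.08) rose, and Armcx2 (-0.6), Inhbb (-0.51), Stc2 (-0.5) and the folate enzyme Aldh1l2 (-0.86; opposite D10Wsu102e) fell. Of 46 p53 targets 14 rose and 0 fell (27 and 0 adjusted over the list alone, median 0.23, adjusted p = 8.6e-19). Of 34 ATF4 targets 14 fell and 0 rose (20 and 1 adjusted over the list alone, median -0.23, adjusted p = 1.3e-12). With an estimated correlation each had an adjusted p of 0.24. With all libraries the p53 list rose with 0 members called (median 0.19, adjusted p = 4e-07, and adjusted p = 0.028 with an estimated correlation) and the ATF4 list fell (median -0.27, adjusted p = 1.4e-08, and adjusted p = 0.18 with an estimated correlation). Of the genes called on ER ribosomes 66 were also called higher and 31 lower in whole-cell RNA without both (1.4 and 0.6 if independent). In the same direction changed 437 of 468 (371 of 468 with all libraries). Both fractions came from the same lysates, so they are not independent and this is no replication.

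Nmd3 siRNA against scramble in whole-cell RNA gave 0 calls by edgeR with all libraries (393 at an unadjusted p under 0.05; DESeq2 0), and scaling by library totals moved the median of all genes from -0.003 to -0.134. Without both libraries (n = 2 after Nmd3 siRNA, n = 3 scramble) 29 genes passed, 11 higher and 18 lower (DESeq2 26). The growth factor Pdgfa (0.45, SE 0.08; opposite 6330403L08Rik), Epop (0.35, SE 0.06), creatine kinase Ckb (0.32) and Cmtm6 (0.38, SE 0.07) rose, and Mroh1 (-0.69, SE 0.09), Prkar2a (-0.43, SE 0.06) and Lef1 (-0.48) fell. With all libraries the large- and small-subunit ribosomal protein lists rose as groups (medians 0.77 and 0.79, adjusted p = 2e-09 and 1e-07), as did the proteasome (0.57, 1.9e-07) and the nuclear-encoded mitochondrial list (0.53, 1.9e-08). With an estimated correlation their adjusted p was 0.67, 0.67, 0.66 and 0.67. Without both libraries the medians were 0, -0.01, 0.05 and 0.03. With the numbers as a block the solute carrier list (adjusted p from 0.049 to 0.06) and the heat shock list (0.046 to 0.061) no longer passed. Their adjusted p with an estimated correlation was 0.73 and 0.66. Of the genes called on ER ribosomes 6 were also called higher and 12 lower without both (0.1 each if independent). In the same direction changed 180 of 204 (135 of 204 with all libraries). Here too both fractions came from the same lysates and are not independent. The direct comparison of the knockdowns in whole-cell RNA gave 0 calls by edgeR (1148 at an unadjusted p under 0.05; DESeq2 1), and 37 without both, 18 higher and 19 lower after Nmd3 siRNA. With all 17 libraries in the fit, with library totals only, or without a filter on low counts, it called 1, Gnl3. The p53 targets were lower without both libraries (0 of 46 higher, 6 lower, median -0.23, adjusted p = 9.9e-11, and adjusted p = 0.24 with an estimated correlation).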

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

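The tests of coding length and carry-over in Nmd3 whole-cell replicate 2 and of both knockdowns, and leaving out both libraries that stood apart, were chosen only after the results were seen. The GC test of Gnl3 whole-cell replicate 3 was set before its result. The results below are lists whose change between ER ribosomes and whole-cell RNA differed between a knockdown and scramble by the interaction test with camera's preset correlation. With an estimated correlation none of them passed. Without both libraries that stood apart, but with the preset correlation, some of these were lost. After Nmd3 siRNA they were the proteasome (adjusted p = 0.46) and nuclear-encoded mitochondrial (0.71) lists. After Gnl3 siRNA it was the mitochondrially encoded mRNAs (0.76). The others still passed, at an adjusted p of 0.035 or less, and none did with an estimated correlation.

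After Nmd3 siRNA the ribosomal proteins were less enriched on ER ribosomes than in scramble cells, with a median interaction of -0.82 for the large subunit (adjusted p = 2.5e-10, and adjusted p = 0.67 with an estimated correlation) and -0.84 for the small subunit (2.5e-08, and 0.67). Without both libraries that stood apart these were -0.06 and -0.05 (adjusted p = 0.0048 and 0.016 with the preset correlation). snoRNA host genes had a median of -0.84 (1.2e-05, and 0.6; -0.17 without both), the nuclear-encoded mitochondrial list -0.51 (1.1e-06, and 0.68; 0 without both) and proteasome subunits -0.48 (1.4e-05, and 0.67; -0.02 without both). Membrane and secretory lists were more enriched: plasma membrane receptors by a median of 0.4 (4.8e-09, and 0.6; 0.16 without both), secreted proteins by 0.33 (0.0015, and 0.6; 0.19 without both), solute carriers by 0.28 (2.8e-05, and 0.6; 0.17 without both) and Golgi enzymes by 0.23 (0.00016, and 0.67; 0.11 without both).

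After Gnl3 siRNA the mitochondrially encoded mRNAs had a median interaction of -0.66 (adjusted p = 0.0019, and adjusted p = 0.66 with an estimated correlation), and 0.11 without both libraries. Primitive endoderm markers had 0.25 (0.033, and 0.3; 0.24 without both), solute carriers 0.14 (0.033, and 0.74; 0.06 without both) and Golgi enzymes 0.12 (0.013, and 0.74; 0.05 without both). With the culture as a block the last 3 had adjusted p = 0.073, 0.099 and 0.051. Without both libraries the ribosomal proteins were also less enriched after Gnl3 siRNA, with medians of -0.13 (1.9e-13) and -0.14 (8.2e-11); with an estimated correlation their adjusted p was 0.51 and 0.5.

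Of the 2 whole-cell libraries that stood apart, which weigh on these interactions, Nmd3 whole-cell replicate 2 was higher in short coding sequences (Spearman's rho -0.66 across genes), but taking off a length trend raised its r with the mean of the other 7 libraries only from 0.872 to 0.925, short of the 0.98 set for a sole cause. Carry-over of ribosome-bound RNA as the sole cause would put nearly every gene that differs between fractions between both means. There 63.4% of 913 such genes lay, within the 25.7% to 67.3% of the other 7 libraries. This test cannot tell whether carry-over made up a part of the difference beside another cause. Gnl3 whole-cell replicate 3 was lower in GC-rich transcripts (rho -0.67), and taking off a GC trend raised its r from 0.898 to 0.935, also short of 0.98. The knockdowns themselves do not set these libraries apart, since the other members of their groups had r of at least 0.991 (Nmd3) and 0.994 (Gnl3) with the scramble libraries. A difference in handling or RNA quality of these libraries may be the source, with length or GC as a part of it, and was not tested.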

How the results depend on the processing

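Leaving out both libraries that stood apart was chosen after the data were seen. All other alternatives were set before the data were examined. Without both, the calls numbered 9197 (scramble enrichment), 9152 (Nmd3 enrichment), 8795 (Gnl3 enrichment), 29 (Nmd3 whole-cell), 142 (Gnl3 whole-cell) and 37 (Nmd3 against Gnl3, whole-cell), against 2353, 2819, 4540, 0, 0 and 0. The spread among the libraries fitted fell with them, from 0.316 to 0.059 in whole-cell RNA. With a replicate block the enrichments gave 386, 1320 and 2975 calls, and on ER ribosomes 126 (Nmd3) and 258 (Gnl3) against 206 and 472. With the block and without both libraries the enrichments gave 8650, 8543 and 8412 calls. With another set of libraries in the fit (for an enrichment only that siRNA's libraries, for the others all 17), calls numbered 9859 (scramble enrichment), 729 (Nmd3 enrichment), 1 (Gnl3 whole-cell), 0 (Nmd3 ER), 1 (Gnl3 ER), 1 (Nmd3 against Gnl3, whole-cell) and 2 (the same on ER ribosomes). Without a filter on low counts they were 1 (Gnl3 whole-cell), 407 (Nmd3 ER), 1 (Nmd3 against Gnl3, whole-cell) and 586 (the same on ER ribosomes). DESeq2 called 1 gene in each of Gnl3 whole-cell and Nmd3 against Gnl3 whole-cell, and library totals called 1 in the latter. Leaving out 1 library at a time gave 541 to 1549 calls (scramble enrichment), 1785 to 5421 (Nmd3 enrichment), 23 to 366 (Nmd3 ER), 70 to 299 (Gnl3 ER) and 159 to 703 (Nmd3 against Gnl3, ER). A lone scramble ER library was then assumed to vary like the other groups. Beyond the change in libraries and genes tested, the cause was not tested. The interaction counts of 0 stayed at 0 under each alternative that changed 1 choice. Without both libraries, the Nmd3 interaction had 1 call with the culture as a block and 2 in DESeq2.

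Of 352 list tests 138 passed. With other settings 133 did with a block and 9 with an estimated correlation. With 256 of the 352 refitted without both libraries, and the ER ribosome tests as before, 142 of 352 passed, and 0 with an estimated correlation. The latter setting thus missed even the 11 mitochondrially encoded mRNAs, all of which fell on ER ribosomes in scramble cells. The simulations tried only the preset correlation, so failing with an estimated one does not show that a list is unchanged. The whole-cell correlation of 0.16 was 0.01 over genes of log2 CPM 5 or more, and 0.38 without both; on ER ribosomes it was 0.59 in both. Of 6806 alternative values for 511 results on single genes, 5744 stayed on the same side of the threshold with the same direction, 950 lost a call, 86 gained one and 26 reversed, 0 of them for a called result.

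The reversed values all belonged to results that were not called in the main test. Without both, Nmd3 under Gnl3 siRNA in whole-cell RNA was -0.05 (0.39 with all; -0.04 to 0.58 leaving out 1 library), Socs3 0.27 (-0.07 with all; -0.33 to 0.28) and the Gnl3 interaction of Nmd3 0.03 (-0.39 with all; -0.58 to 0.05). Dnmt3l under Gnl3 siRNA in whole-cell RNA was 0 with library totals and 0 with a block (0.04 in the main test; -0.09 to 0.26 leaving out 1 library). Leaving out 1 library also reversed, in Gnl3 whole-cell RNA, Phlda3 (-0.08 to 0.58), Epha2 (-0.03 to 0.35), Mgat4b (-0.12 to 0.32) and Neat1 (-0.04 to 0.43), and in Nmd3 whole-cell RNA Dnajb14 (opposite Gm25920, -0.57 to 0.03) and Cd24a (-0.4 to 0.04). On ER ribosomes it reversed Gnl3 under Nmd3 siRNA (-0.02 to 0.37) and Nmd3 under Gnl3 siRNA (-0.04 to 0.01). It further reversed the Nmd3 interaction of Gnl3 (-0.22 to 0.2) and Tfcp2l1 between the knockdowns in whole-cell RNA (-0.11 to 0.42). Low counts limit what can be called. In simulated data for Nmd3 siRNA against scramble on ER ribosomes, 2-fold changes were found in 6% of genes under a log2 CPM of 1, 86% from 1 to 4 and 100% above. In whole-cell RNA 0% were found at each level with all libraries, and 24%, 82% and 100% without both, so there the spread among libraries was the limit. This simulation by level was chosen after the data were seen.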

Other observations

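The tests of counts in genes opposite an abundant gene (the ratio to the expected count, and entries with no feature) were chosen only after the results were seen. The tests of length and GC in the secretory lists and the splits were set before. After Gnl3 siRNA some further lists changed on ER ribosomes. Of 24 primitive endoderm markers 4 rose and 0 fell, as over the list alone (median 0.23, adjusted p = 0.00026, and adjusted p = 0.4 with an estimated correlation), among them the basement membrane collagen Col4a1 (0.49; opposite Col4a2) and the keratin Krt19 (0.78). Of 18 fibroblast and feeder markers 2 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.27, adjusted p = 0.00087, and adjusted p = 0.18 with an estimated correlation), Thbs1 (opposite Gm29233) by 0.5 and Cald1 by 0.36. Of 37 cytoskeleton genes 4 rose and 0 fell, as over the list alone (median 0.03, adjusted p = 0.029, and adjusted p = 0.67 with an estimated correlation), Vim by 0.37 and Msn (opposite Gm24718) by 0.29. The 21 totipotent 2-cell-like genes had a median of 0.4 with 0 called (2 and 0 adjusted over the list alone; adjusted p = 0.00083, and adjusted p = 0.33 with an estimated correlation). Otx2, an epiblast factor, fell (-0.53; opposite Otx2os1), and Abcb1b, a drug exporter, rose (0.47; opposite Gm5106).

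After Nmd3 siRNA snoRNA host genes fell on ER ribosomes (2 of 17 fell, 0 rose; 6 and 0 adjusted over the list alone, median -0.17, adjusted p = 0.00087, and adjusted p = 0.51 with an estimated correlation), Zfas1 (-0.25; opposite Znfx1) and Snhg5 (-0.24) among them. ER chaperones had a median of 0.13 with 0 called (6 and 1 adjusted over the list alone; adjusted p = 0.00058, and adjusted p = 0.67 with an estimated correlation), and solute carriers 0.15 with 1 of 46 called higher (3 and 0 adjusted over the list alone; adjusted p = 5.1e-05, and adjusted p = 0.73 with an estimated correlation), the exporter Abcb1b by 0.49. Otx2 (-0.46) and Meg3 (-0.38; opposite Gm26906) fell and Tbx3 (0.33; opposite Tbx3os1) rose. In whole-cell RNA without both libraries that stood apart the mitochondrially encoded mRNAs had a median of -0.39 after Nmd3 siRNA (adjusted p = 2.6e-05, and adjusted p = 0.55 with an estimated correlation), with 1 of 11 lower adjusted over the list alone. Of the 2 Nmd3 siRNA libraries left only replicate 1 was low, with mitochondrial RNA at 1.15% of counts, while replicate 3 was at 1.92%, within the 1.86% to 2.03% of the scramble libraries.

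Enrichment on ER ribosomes in scramble cells was lower for longer coding sequences (Spearman's rho -0.59 across 11907 genes) and higher with GC content (0.31). Whether these trends could account for the 6 secretory and membrane lists was tested by taking each off with a loess: 6 of 6 lists kept a median of at least 0.2 after length and 6 of 6 after GC. After length the medians were 0.67 (ER chaperones), 0.69 (secreted), 0.66 (plasma membrane), 0.42 (solute carriers), 0.47 (Golgi) and 0.77 (lysosomal). The ribosomal protein lists, by contrast, went from 0.44 and 0.45 to 0.02 and 0.06, the nuclear-encoded mitochondrial list from 0.3 to 0.01 and the p53 targets from 0.19 to 0.08, so length may be enough for those. Enrichment of mRNAs that encode ER-translocated proteins remains a hypothesis for the 6 lists, and other technical sources such as polyA selection were not tested.

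Genes lying opposite an abundant gene carried counts: over 37 such pairs in scramble whole-cell replicate 2, a median of 1.5 times the count expected from the gene opposite (95% interval 1.26 to 1.94), and their enrichment followed that of the gene opposite (rho 0.73 over 32 pairs). Counting without strand would give such a rho, but HTSeq in its default mode would then set a read over both genes aside as ambiguous and leave a ratio of at most 0.5. The medians were 0.59 to 1.66 over the 17 libraries, but the lower bound of the interval fell to 0.22, so counting without strand stays open. Another candidate explanation is that each mate of a pair was counted on its own with strand, which would leave about as many entries with no feature as gene counts, and that ratio had a median of 1.06 over the 17 libraries (1.015 to 1.088). The counting command is not stated, and values of genes with such a partner are uncertain.

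With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the whole-cell comparisons 10 of the 10 splits gave as many calls as the real one (0, highest other 0). For Nmd3 against Gnl3 on ER ribosomes 1 of 10 did (real 387, highest other 0), and for the Gnl3 enrichment 1 of 10 (real 4540, highest other 0). For the Nmd3 enrichment 1 of 10 did (real 2819, highest other 306, in the split that exchanges Nmd3 whole-cell replicate 2 with ER ribosome-bound replicate 2). The comparisons that use the scramble ER libraries have 2 libraries in a group and were not split.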
